A study of Mus musculus with 18 samples.

How the data were processed

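RNA was sequenced from 4 sorted mouse populations (strain B6SJL), with 3 libraries each. They were burst-forming erythroid progenitors (BFU-E) from steady-state bone marrow (BM), and multipotent progenitors (MPP), BFU-E and colony-forming erythroid progenitors (CFU-E) from spleens at day 8 after irradiation and transplantation. Accessible chromatin was profiled by ATAC-seq in the steady-state and stress BFU-E, also with 3 libraries each. Per the labels' protocols, cells were depleted of lineage-positive cells and sorted by flow cytometry, libraries were made with a stranded total RNA kit for low input, and the steady-state sorts used another fluorophore for the biotinylated antibodies than the spleen sorts. Tissue, irradiation and that staining change together between the BFU-E populations.

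Per the submitters' processing notes, STAR 2.6.0b-1, Bowtie2 2.3.4.2, HOMER 4.8 and DESeq2 were used on mouse build mm10 (GRCm38), without a version for DESeq2 and without saying which step each tool served. Per the file headers, the authors made the RNA tables with HOMER's counting over exons, with 1 transcript kept per gene. The counting strand is not stated, so a gene and its antisense partner could not be told apart. The deposited count tables hold raw, unnormalised counts per gene: one holds the 9 spleen libraries, and the other holds both BFU-E populations and only genes that the authors kept on a mean of 50 counts. In the values, that filter matched a mean of 50 in at least 1 of the 2 populations. The deposited RPKM tables hold reads scaled to gene length and library size, in one table for all 12 libraries and in another for the 6 BFU-E libraries; in the latter, 1 of the BM columns carries no complete library name and was used as a member of its group without a number. The deposited ATAC lists hold 1 merged peak list per population with a score per peak, from 415 to 1000, and HOMER annotation; the file names mention the irreproducible discovery rate (IDR), but the peak caller and the IDR threshold are not stated. Repeated entries for 1 interval were merged, which left 35142 of 76147 entries for BM and 61661 of 117426 for stress spleen.

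Differences between groups of counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, quasi-likelihood F test), and p-values were adjusted by the Benjamini-Hochberg method (BH) with a threshold of 0.05. The BFU-E comparison used the 10702 genes the authors kept. The 3 spleen populations were fitted together on the 10166 genes with a mean of 50 or more counts over the 9 libraries. Gene levels are given as CPM (counts scaled to a common library size, with TMM factors), as mean ± SD over 3 libraries. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. It is an approximation, and for genes near 0 counts in a group it can be too small. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and BH adjustment over the lists with at least 5 tested members; 36 lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. That rule took the 10 largest rises and falls with an adjusted p under 0.05, a mean CPM of at least 20 and no overlap between the groups, without gene models that carry only a clone or predicted-gene name. It also took up to 3 members per direction and list, the 2 most abundant members of a list in which none passed, and the genes of the antigens used for sorting. The part of these genes that is printed was picked after their values were seen. Some genes that the rule named are not reported here. BM BFU-E was compared with MPP and CFU-E in limma on log2(RPKM + 1), for genes with an RPKM of at least 1 in at least 3 libraries.

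The place of the BFU-E libraries between MPP and CFU-E was the median over genes of (level − MPP mean)/(CFU-E mean − MPP mean) on log2(RPKM + 1). Its genes had at least a 4-fold difference and an adjusted p under 0.05 between MPP and CFU-E in an edgeR fit without any BFU-E library, and a difference of at least 0.5 on that scale. The BFU-E values came from the RPKM table of both BFU-E populations alone, a choice made after the BM columns of the RPKM tables were seen to differ; the other columns were an alternative. It was tested with an exact two-sided permutation test, for which 3 against 3 libraries allow no p below 0.1. Peak lists were compared with bedtools 2.31.1, counting an overlap of at least 1 bp as shared. Distal peaks lay over 1 kb from a transcription start site (TSS). For 12 consensus motifs, the share of peaks with a match within 100 bp of the peak centre was compared by two-sided Fisher's exact tests with scipy 1.17.1, adjusted over 72 tests; the units of those tests are peaks, not libraries. Shares of peaks carry 95% Wilson intervals, which cover counting error only. A gene with a count of 0 in a whole group was compared with a floor of 3 counts over the group.

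The fits were tested on simulated counts with known changes in 200 genes. With the spread of the BFU-E comparison over 10702 genes, edgeR recovered 0% of 2-fold, 25.4% of 4-fold and 36.4% of 8-fold changes, and 1 of its 42 calls was false. For BFU-E against MPP over 10166 genes, it recovered 59.7%, 86.6% and 98.5% at those sizes, with 11 false calls of 174. For CFU-E against BFU-E over 10166 genes the recovered shares were 56.7%, 86.6% and 100%, with 12 false of 174. For CFU-E against MPP they were 50.7%, 94.0% and 98.5%, with 14 false of 176. On simulated RPKM of 11628 genes, limma recovered 35.8% of 2-fold, 89.6% of 4-fold and 95.5% of 8-fold changes for BM against MPP, and 32.8%, 91.0% and 95.5% for BM against CFU-E. Camera was tested on 20 simulated lists of 20 genes, which varied independently of each other, as genes of real lists may not. For the BFU-E comparison it found 9 of the 10 lists changed by 1.5-fold and 0 of the 10 unchanged lists. For CFU-E against BFU-E it found 10 changed lists and 2 unchanged ones.

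The alternatives covered DESeq2 1.42.0 (its size factors and its Wald test), a model with the replicate number as a block, a minimum of 2-fold, other filters on low counts, limma on RPKM, voom with quality weights, camera with an estimated correlation, fry, other pseudocounts, other definitions of shared peaks, a window of 250 bp for motifs, and leaving out each library in turn. Added after the data were seen were voom with quality weights, fits without non-coding RNA, the BM columns of the other RPKM table, the place of the BFU-E without genes of myeloid, macrophage and antigen presentation lists, alone or together with genes lower in stress, a mean dispersion trend in DESeq2, and peaks drawn to equal GC content. DESeq2's default dispersion trend for the BFU-E comparison was reached or not depending on the number of computing threads, and it called far fewer genes where it was reached, so the local trend was fixed there. The labels do not say whether the replicate numbers pair libraries, and the main fits used no pairs. After removal of group means, BFU-E libraries of the 2 tissues correlated across genes at −0.036 to −0.030 with the same number and at −0.012 to 0.044 with different numbers. In the spleen table the values were 0.015 to 0.116 and −0.090 to 0.030, so a weak pairing of the spleen libraries stays possible. Globin genes have near-identical copies that share reads, and none of that list was among the genes tested on counts. ATAC libraries could not be compared one by one, since each list merges 3 of them.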

Results

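Stress erythropoiesis is the rapid making of red cells that follows blood loss, infection or transplantation, and in mice it takes place mostly in the spleen. Its early steps pass from multipotent progenitors (MPP) through burst-forming (BFU-E) to colony-forming (CFU-E) erythroid progenitors, which are defined by the colonies they form and are sorted here by surface antigens. RNA was sequenced from 3 libraries each of steady-state bone marrow (BM) BFU-E and of stress spleen MPP, BFU-E and CFU-E, taken at day 8 after irradiation and transplantation, and chromatin accessibility of both BFU-E populations was profiled by ATAC-seq. The BM BFU-E libraries held 9463498, 8385818 and 6758871 counts, and the spleen BFU-E libraries held 12926718, 10555143 and 12188446, over the genes of the BFU-E table. The MPP libraries held 13197159, 5937778 and 8566125 counts, and the CFU-E libraries 12663624, 11933467 and 9884686, over all genes of the spleen table. The ribosomal RNA precursor Rn45s took 8.01% to 15.2% of the counts in BM BFU-E, 10.6% to 11.5% in spleen BFU-E, 16.0% to 22.6% in MPP and 10.3% to 12.9% in CFU-E. The shares of other non-coding RNAs did not overlap between the BFU-E populations: the RNase P RNA Rpph1 took 0.449% to 1.68% in BM and 0.119% to 0.200% in spleen BFU-E, and small nucleolar RNAs 0.167% to 0.244% and 0.0401% to 0.0582%, so these RNAs differ along with tissue and stress. Across the genes of the BFU-E table, the BM libraries correlated with each other at 0.669 to 0.789 (mean 0.722), the spleen libraries at 0.958 to 0.964, and BM with spleen libraries at 0.707 to 0.878 (mean 0.796), higher on average than BM libraries with each other (Pearson's r of log2 values across genes, which are not independent replicates). In BM libraries 1, 2 and 3, 5.81%, 1.53% and 15.3% of these genes had a count of 0, against 0.420% to 0.738% in the spleen libraries. Among the BM libraries the share of Rpph1 had the same order, lowest in BM 2 and highest in BM 3. It may therefore also follow the quality of the libraries, which was not tested. The share of small nucleolar RNAs was highest in BM 1. Depth per ATAC library is not given in the files.

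The first comparison asks how BFU-E made in the spleen under stress differ from BFU-E of the resting marrow. In this comparison tissue, irradiation with transplantation, and the staining of the sort change together. Of 10702 genes, edgeR (quasi-likelihood, BH adjustment) called 12, with 1 higher and 11 lower in stress spleen BFU-E. At an unadjusted p under 0.05 there were 1053 genes, 410 higher and 643 lower, and in 2341 genes (21.9%) the groups did not overlap. Chance gives 10% for genes kept without regard to group. The authors' filter appears to have used the mean of each population, so 10% is only a rough mark here. DESeq2 called 685 genes, and in simulated counts with this spread 571 of its 676 calls were false. The edgeR count moved with single libraries: it was 4 without BM 1, 5 without BM 2, 27 without BM 3, 7 without stress spleen BFU-E 1, 0 without stress spleen BFU-E 2 and 0 without stress spleen BFU-E 3. In those last fits 481 and 489 genes had an unadjusted p under 0.05. Without non-coding RNA 9 genes were called, 1 higher and 8 lower. The spread of the pair was wide, with a biological coefficient of variation of 0.704 against 0.250 over the spleen populations.

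The gene that rose in stress spleen BFU-E was Ctse, which encodes the aspartic protease cathepsin E (mm10 chromosome 1, 131638314 to 131675507). It measured 102 ± 2.36 CPM in spleen against 14.3 ± 3.57 in BM (SD, n = 3 each; log2 fold change 2.84, SE 0.33, edgeR adjusted p = 0.032). Csf1r, the receptor for macrophage colony-stimulating factor (chromosome 18, 61105572 to 61131139), measured 9.35 ± 0.240 against 92.5 ± 37.4 CPM (log2 fold change −3.31, SE 0.41, edgeR adjusted p = 0.037). F13a1, the A chain of coagulation factor XIII (chromosome 13, 36867178 to 37049213), was at 31.0 ± 6.49 against 327 ± 98.8 CPM (−3.40, SE 0.30, edgeR adjusted p = 0.020). The galectin gene Lgals1 changed by −3.15 and Unc93b1, which carries endosomal Toll-like receptors to their compartment, by −2.72. Tifab, a regulator of innate immune signalling, changed by −3.43. Itsn1 (−2.14), Nol4l (−1.87) and the nuclear non-coding RNA Neat1 (−1.84) were also lower in stress. Each of these 9 genes lost its call without at least 1 library. For Ctse the edgeR adjusted p was 0.067 without BM 1, 0.067 without BM 2, 0.16 without stress spleen BFU-E 1, 0.29 without stress spleen BFU-E 2 and 0.27 without stress spleen BFU-E 3. For Csf1r it was 0.13, 0.078, 0.17, 0.29 and 0.27 without the same libraries. F13a1 lost its call without BM 2 (0.067), stress spleen BFU-E 2 (0.23) and stress spleen BFU-E 3 (0.15). Lgals1, Unc93b1, Itsn1, Nol4l and Neat1 kept theirs only without BM 3, and Tifab only without BM 1 or BM 3. The highest adjusted p of these came without stress spleen BFU-E 2 (0.23 for Unc93b1, 0.27 for the others).

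**Figure D1:**
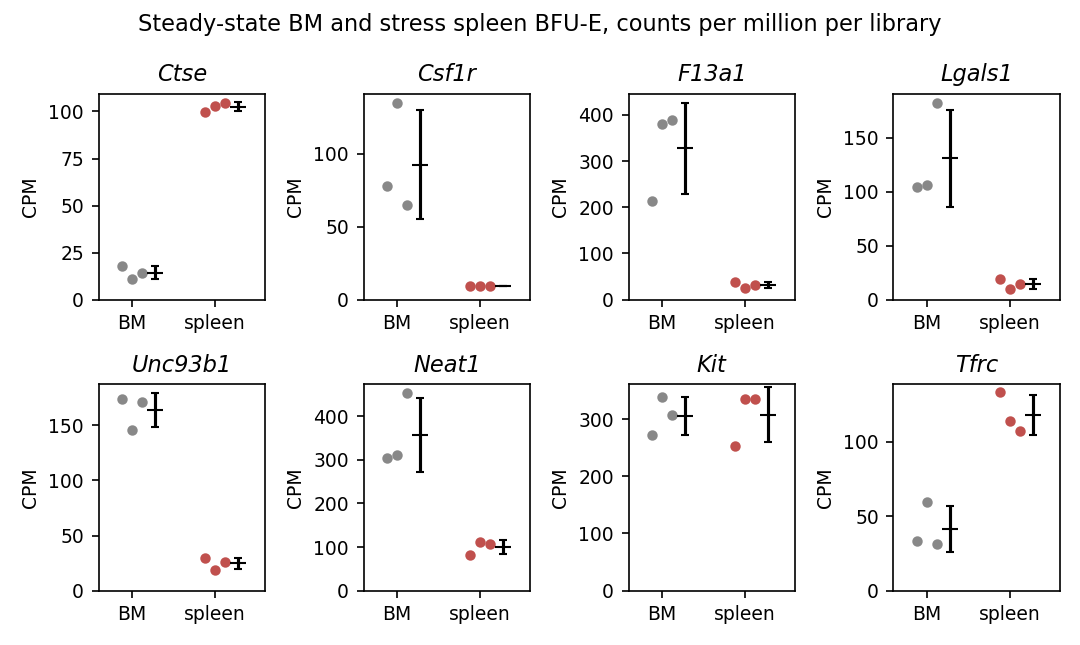
CPM of 8 genes in the 3 libraries of steady-state BM BFU-E (BM) and the 3 of stress spleen BFU-E (spleen), as points, with mean and SD beside them. Ctse was higher in spleen (102 against 14.3 CPM), Csf1r, F13a1, Lgals1, Unc93b1 and Neat1 were lower, and Kit and Tfrc did not pass the test.

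The antigens used for sorting set what the gates held alike. Kit, the stem cell factor receptor, was at 308 ± 47.5 CPM in spleen and 305 ± 32.7 in BM BFU-E (log2 fold change 0.01, edgeR adjusted p = 0.99). The transferrin receptor Tfrc (CD71) was at 118 ± 13.5 against 41.2 ± 15.6 CPM (1.51, edgeR adjusted p = 0.21) and did not pass the test. Slamf1 (1.13), Cd24a (−1.29) and Cd9 (−0.10) did not pass it either. The list of sort antigens did not move one way as a whole (5 tested members, median log2 fold change 0.01, camera adjusted p = 0.57). Adjusted over the list alone 2 members rose and 1 fell, and fry's test for change in either direction gave an adjusted p of 0.0035.

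Of the gene lists, 12 passed camera at the preset correlation, 4 higher and 8 lower in stress, and with an estimated correlation 0 of them did. fry, which tests whether a list's genes move one way on balance, called 3: nucleotide synthesis (fry adjusted p = 0.022) and the unfolded protein response (0.0089) of these 12, and the S phase list (0.048), which camera did not call (adjusted p = 0.36). The myeloid markers, genes of monocytes and granulocytes, were lower in stress spleen BFU-E. Of 17 tested members 16 were lower, with a median log2 fold change of −1.51 (camera adjusted p = 4e-10, adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone, 8 of them fell, and over all genes 1 did. The macrophage markers were lower in 8 of 8 members (median −3.68, camera adjusted p = 0.00033, adjusted p = 0.32 with an estimated correlation). The list of nucleotide and one-carbon synthesis, which supplies DNA precursors, was higher in 19 of 23 members (median 0.53, camera adjusted p = 0.0003, adjusted p = 0.31 with an estimated correlation), and 4 of them rose adjusted over the list alone. The unfolded protein and integrated stress response list was lower in 11 of 17 (median −0.39, camera adjusted p = 0.013, adjusted p = 0.32 with an estimated correlation), and 4 fell adjusted over the list alone. These 4 lists kept their camera call without each single library. The other 8 lost it without at least 1. Oxidative phosphorylation (median 0.50) and the cytokine and growth factor receptors (median −0.47) lost it without BM 2, at 0.11 and 0.060. Glycolysis (median 0.38) lost it without BM 1, at 0.11. The immediate early response (median −0.40) and adhesion and homing (median −0.23) lost it without BM 2, at 0.10 and 0.25. Antigen presentation (17 members, 11 lower, median −0.12) lost it without BM 2 (0.25), BM 3 (0.31) and stress spleen BFU-E 2 (0.059). The stem and multipotent progenitor list (median −0.24) lost it without BM 1 (0.090) and BM 2 (0.25). The histones (median 0.32) lost it without BM 1 (0.19), BM 2 (0.66) and stress spleen BFU-E 1 (0.13). With an estimated correlation, the adjusted p of these 8 lists lay between 0.32 and 0.46.

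The erythroid lists did not pass camera between the BFU-E populations. The erythroid transcription regulators had a median log2 fold change of −0.06 and a mean of −0.05, while camera's direction was up (adjusted p = 0.85). Haem synthesis (median 0.03, camera adjusted p = 0.85), iron uptake and storage (−0.07, 0.71) and red cell membrane genes (0.35, 0.12) did not pass either. Adjusted over the list alone, 3 erythroid regulators and 2 iron genes rose and 0 fell, and fry's test for change in either direction gave an adjusted p of 0.0081 for both lists, 0.031 for red cell membrane genes and 0.089 for haem synthesis. The BMP list, whose pathway drives the expansion of stress progenitors in the spleen, had a median of −0.03 (camera adjusted p = 0.35), and the hedgehog and WNT list a median of 0.40 (0.092). For hypoxia the median was −0.07 and the mean 0.19, and for the glucocorticoid response the median was −0.10 and the mean 0.22; neither list passed. With this spread, edgeR recovered 0% of simulated 2-fold changes in single genes tested over all genes. Camera recovered 9 of 10 simulated lists changed by 1.5-fold, but those simulated genes varied independently of each other. Genes of real lists can move together, so this recovery does not show that camera could see such a change in them.

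The spleen populations follow the path from multipotent cell to committed erythroid progenitor under stress. MPP carry programs of stem cells, and BFU-E are the first stage limited mostly to the erythroid line. BFU-E against MPP gave 420 of 10166 genes, 206 higher and 214 lower in BFU-E (edgeR, BH). At an unadjusted p under 0.05 there were 1611, and in 2171 genes (21.4%) the groups did not overlap, where chance gives 10%. The count was 225 without BFU-E 1, 247 without BFU-E 2 and 254 without BFU-E 3. The regulators of stem cells were lower in BFU-E. Hlf (chromosome 11, 90336535 to 90390917) measured 13.19 ± 3.66 CPM in BFU-E against 100.7 ± 14.5 in MPP (log2 fold change −2.93, SE 0.25, edgeR adjusted p = 2.2e-07). Mecom, which encodes Evi1 (chromosome 3, 29951296 to 30013204), measured 23.2 ± 6.71 against 114 ± 8.66 CPM (−2.301, SE 0.22, edgeR adjusted p = 8.2e-07). Prdm16 changed by −2.66, the endothelial protein C receptor gene Procr by −6.74 and the guanine exchange factor Fgd5 by −4.36. The collagen genes Col4a1 and Col4a2 changed by −2.49 and −3.51, and the homeobox gene Nkx2-3 by −3.72. Ly6a (Sca1), by which MPP were sorted, was at 0.286 ± 0.373 against 19.8 ± 1.28 CPM (−6.02, edgeR adjusted p = 0.00027).

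Some erythroid genes rose at this step. Klf1, the erythroid Krüppel-like factor (chromosome 8, 84901928 to 84905295), was at 28.6 ± 4.65 CPM in BFU-E against 12.1 ± 4.99 in MPP (log2 fold change 1.24, SE 0.23, edgeR adjusted p = 0.0028). Tal1 rose by 0.52 (0.0041), the water channel Aqp1 by 0.94 (3.5e-05) and the iron reductase Steap3 by 0.95 (0.0020, all edgeR adjusted). The actin regulator Scin rose by 3.93, from 3.95 ± 3.30 to 67.6 ± 9.55 CPM, the autophagy receptor Optn by 2.25 and the TGF-beta binding protein gene Ltbp1 by 3.20. Il1rl1, the receptor for interleukin 33, rose by 3.04 (edgeR adjusted p = 0.00016). Genes of the megakaryocyte line rose as well: Itga2b (CD41, chromosome 11, 102453297 to 102469883) was at 756 ± 32.2 against 373 ± 41.5 CPM (1.02, SE 0.10, edgeR adjusted p = 1.1e-06), Plek rose by 1.39 and the fibrinogen receptor subunit Itgb3 by 1.30. Cd24a changed by −1.63 (2.7e-06). Cd9 rose by 0.90 (edgeR adjusted p = 0.0095) and Kit fell by 0.51 on the log2 scale (edgeR adjusted p = 0.0090). Both lost the call without BFU-E 1 (adjusted p = 0.0735 and 0.0769). Tfrc (0.49, edgeR adjusted p = 0.083) and Slamf1 (−0.54, edgeR adjusted p = 0.34) did not pass.

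**Figure D2:**
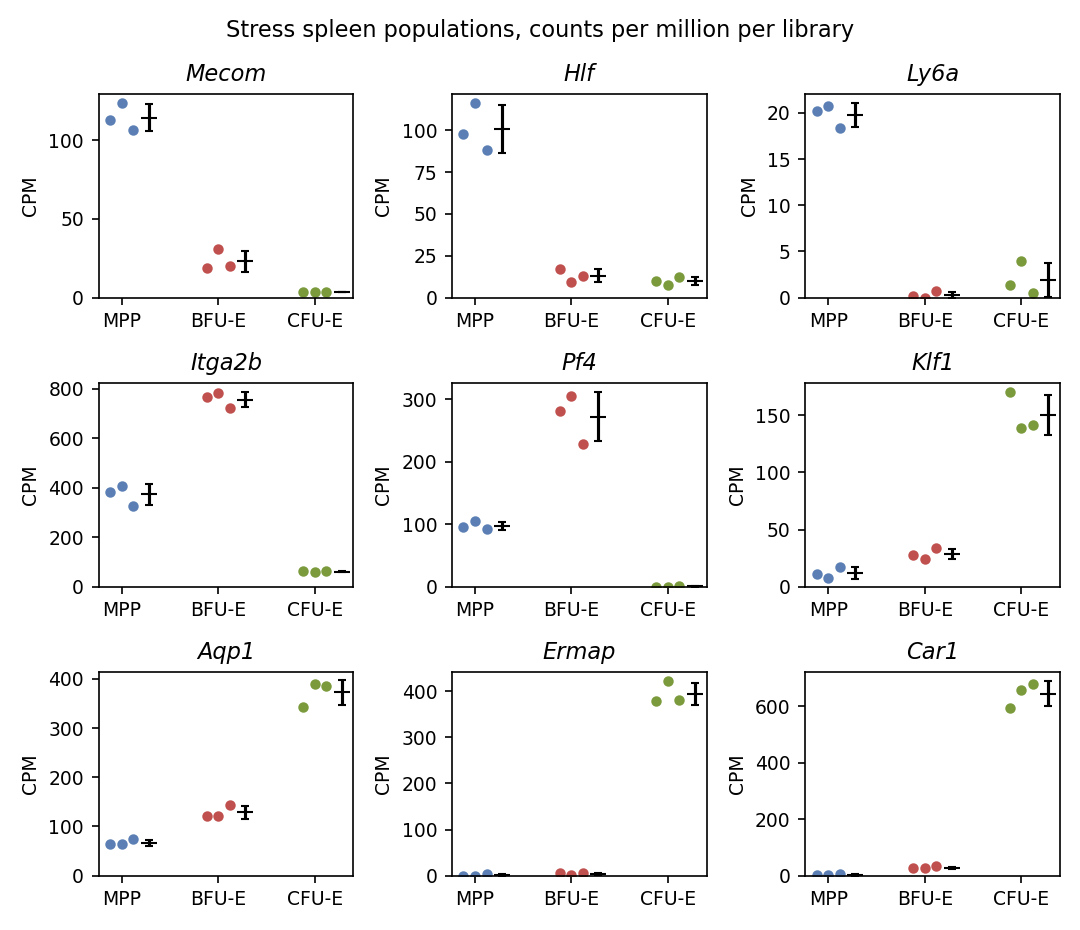
CPM of 9 genes in the 3 libraries each of stress spleen MPP, BFU-E and CFU-E, as points, with mean and SD beside them. Mecom fell at each step, Hlf from MPP to BFU-E, Itga2b and Pf4 were highest in BFU-E, and Klf1, Aqp1, Ermap and Car1 were highest in CFU-E.

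Of the lists for BFU-E against MPP, 13 passed camera at the preset correlation, and 4 passed with an estimated correlation too. The megakaryocyte markers were higher in BFU-E in 14 of 17 members (median 1.02, camera adjusted p = 2.7e-17); 8 rose over all genes and 11 adjusted over the list alone. Red cell membrane and blood group genes were higher in 10 of 13 (median 0.87, camera adjusted p = 9.4e-17), and 7 rose. The interferon response list, genes induced by antiviral signalling, was lower in 26 of 28 (median −0.65, camera adjusted p = 1.1e-11), 6 of them past the threshold over all genes and 13 adjusted over the list alone. Among them were Oasl2 (−1.76) and the guanosine triphosphatase Iigp1 (−2.18). The stem and multipotent progenitor list was lower in 20 of 26 (median −0.72, camera adjusted p = 1.1e-11), and 8 fell. With an estimated correlation their adjusted p was 0.018, 0.018, 0.018 and 0.021. The replication-dependent histones, made in S phase, were higher in 21 of 25 (median 0.44, camera adjusted p = 5.2e-08, adjusted p = 0.30 with an estimated correlation), and 7 rose. The erythroid transcription regulators were higher in 13 of 17 (median 0.09, camera adjusted p = 0.0084, adjusted p = 0.30 with an estimated correlation), and 4 rose over all genes. Haem synthesis (1 of 14 rose, camera adjusted p = 0.297), iron uptake and storage (2 of 13, 0.125) and the erythropoietin receptor and STAT5 targets (0 of 16, 0.66) did not pass. The sort antigens had a median of −0.52 (0.0023, adjusted p = 0.069 with an estimated correlation). The other 6 lists lost their call also without 1 library, at their highest adjusted p as follows: adhesion and homing (0.178) and CDK inhibitors (0.178) without MPP 3, antigen presentation (0.0664) without BFU-E 2, and oxidative phosphorylation (0.0919), nucleotide synthesis (0.0999) and red cell maturation (0.0919) without MPP 1. The myeloid markers (15 members, median 0.03, camera adjusted p = 0.18) did not pass.

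CFU-E are the last colony-forming stage before the dividing erythroblasts, and they depend on erythropoietin. Of the 10166 genes, 2145 differed between CFU-E and BFU-E, 932 higher and 1213 lower in CFU-E (edgeR, BH). At an unadjusted p under 0.05 there were 3231, and in 3809 genes (37.5%) the groups did not overlap, where chance gives 10%. The erythroid membrane protein gene Ermap (chromosome 4, 119175457 to 119190011) measured 393 ± 24.3 CPM in CFU-E against 4.06 ± 2.01 in BFU-E (log2 fold change 6.57, SE 0.35, edgeR adjusted p = 9.7e-12). Carbonic anhydrase Car1 (chromosome 3, 14766214 to 14778460) measured 644 ± 44.3 against 28.5 ± 3.90 CPM (4.50, SE 0.26, edgeR adjusted p = 4.5e-11). The red cell pyruvate kinase Pklr rose by 6.73, the ankyrin gene Ank1, which anchors the spectrin skeleton, by 4.55, and the metallothionein Mt2 by 4.52. Klf1 rose again, to 150 ± 17.5 CPM (2.40, SE 0.23, edgeR adjusted p = 7.9e-08), and Ikzf1 by 1.13. For iron and haem, Tfrc was at 293 ± 39.9 against 116 ± 13.6 CPM (1.34, SE 0.15, edgeR adjusted p = 1.3e-06), Tfr2 rose by 1.15, and the haem enzymes Alad and Cpox by 1.76 and 1.58. The erythropoietin receptor Epor rose by 1.29 (edgeR adjusted p = 0.0012), whereas the survival gene Bcl2l1, a STAT5 target, changed by −2.41 (2.5e-08). The spectrin gene Sptb, another member of the red cell membrane list, changed by −1.89 (4.7e-05).

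Genes of platelet biology were far lower in CFU-E than in BFU-E. CFU-E were sorted by the absence of Cd9, so a step on the path and the gate cannot be told apart here. Platelet factor 4, Pf4 (chromosome 5, 90772435 to 90773383), was at 0.359 ± 0.482 CPM in CFU-E against 272 ± 39.4 in BFU-E (log2 fold change −9.68, SE 0.32, edgeR adjusted p = 6.5e-15). With each library left out in turn, the log2 fold change of Pf4 ran from −11.52 to −9.16, wider than that SE. Itga2b was at 60.9 ± 2.78 against 756 ± 32.2 CPM (−3.63, SE 0.11, edgeR adjusted p = 1.2e-15). Itgb3 changed by −7.00, the von Willebrand factor gene Vwf by −5.04 and the metalloproteinase inhibitor Timp3 by −10.10. The homeobox gene Meis1, which acts in stem cells and megakaryocytes, changed by −2.01 and Mycn by −2.77, while Myc rose by 0.87 (431 ± 29.9 against 235 ± 23.4 CPM, edgeR adjusted p = 2.3e-06). Mllt3, a regulator of stem cells on the same list as Meis1, rose by 1.17. The folate enzyme Mthfd1 rose by 1.22, the glucocorticoid receptor Nr3c1 by 0.81 and cyclin E1, Ccne1, by 1.92, whereas cyclin B2, Ccnb2, changed by −0.77 and the pyruvate kinase Pkm by −1.64. The myeloid genes Lyz2 and Irf8 changed by −3.50 and −5.55. Of the sorting antigens, Cd9, by whose absence CFU-E were sorted, was at 18.7 ± 7.34 against 149 ± 14.0 CPM (−2.98, edgeR adjusted p = 1.2e-09), Cd24a rose by 2.296 and Kit by 0.70. Slamf1 changed by −0.81 (edgeR adjusted p = 0.036) and lost its call without BFU-E 1 (0.18), BFU-E 3 (0.061), CFU-E 1 (0.17) and CFU-E 2 (0.082). Ly6a, at 1.94 against 0.286 CPM (2.69, edgeR adjusted p = 0.031), lost it without BFU-E 1 (0.121), BFU-E 2 (0.110) and CFU-E 2 (0.239).

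Of the lists for CFU-E against BFU-E, 16 passed camera at the preset correlation and 7 with an estimated correlation. The megakaryocyte markers fell in 17 of 17 members (median −4.40, camera adjusted p = 1.6e-107, with an estimated correlation 0.00036). Stem and multipotent progenitor genes were lower in 23 of 26, and 15 fell (median −1.29, camera adjusted p = 7.7e-15, with an estimated correlation 0.010). Ribosome biogenesis and MYC genes, which raise the capacity for protein synthesis, were higher in 26 of 26, and 17 rose (median 0.48, camera adjusted p = 5.5e-08, with an estimated correlation 0.0097). Red cell membrane genes were higher in 11 of 13 (median 1.53, camera adjusted p = 8e-12), iron genes in 10 of 13 (median 0.53, 9.4e-05) and haem synthesis genes in 13 of 14 (median 0.42, 0.00086); with an estimated correlation their adjusted p was 0.030, 0.030 and 0.038. Adhesion and homing genes were lower in 12 of 17 (median −0.28, camera adjusted p = 5.4e-06, with an estimated correlation 0.030). S phase genes were higher in 25 of 30 (median 0.19, camera adjusted p = 0.0046, adjusted p = 0.23 with an estimated correlation). The erythropoietin receptor and STAT5 target list was lower in 11 of 16 (median −0.57, camera adjusted p = 0.010, adjusted p = 0.17 with an estimated correlation). Myeloid markers were lower in 15 of 15 (median −2.79, camera adjusted p = 3.2e-06, adjusted p = 0.23 with an estimated correlation). Nucleotide synthesis (median 0.32), the erythroid regulators (0.49) and the glucocorticoid response (0.14) were higher, at adjusted p = 0.27, 0.23 and 0.24 with an estimated correlation. Mitosis genes (median −0.28) lost their camera call without BFU-E 1 (0.0598) and CFU-E 3 (0.0747), antigen presentation (median −0.23) without CFU-E 3 (0.0675), and oxidative phosphorylation (median 0.24) without BFU-E 3 (0.0600) and CFU-E 1 (0.0934); with an estimated correlation their adjusted p was 0.32, 0.23 and 0.24. For glycolysis the median was 0.09 and the mean −0.19, and the list did not pass (camera adjusted p = 0.53).

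**Figure D3:**
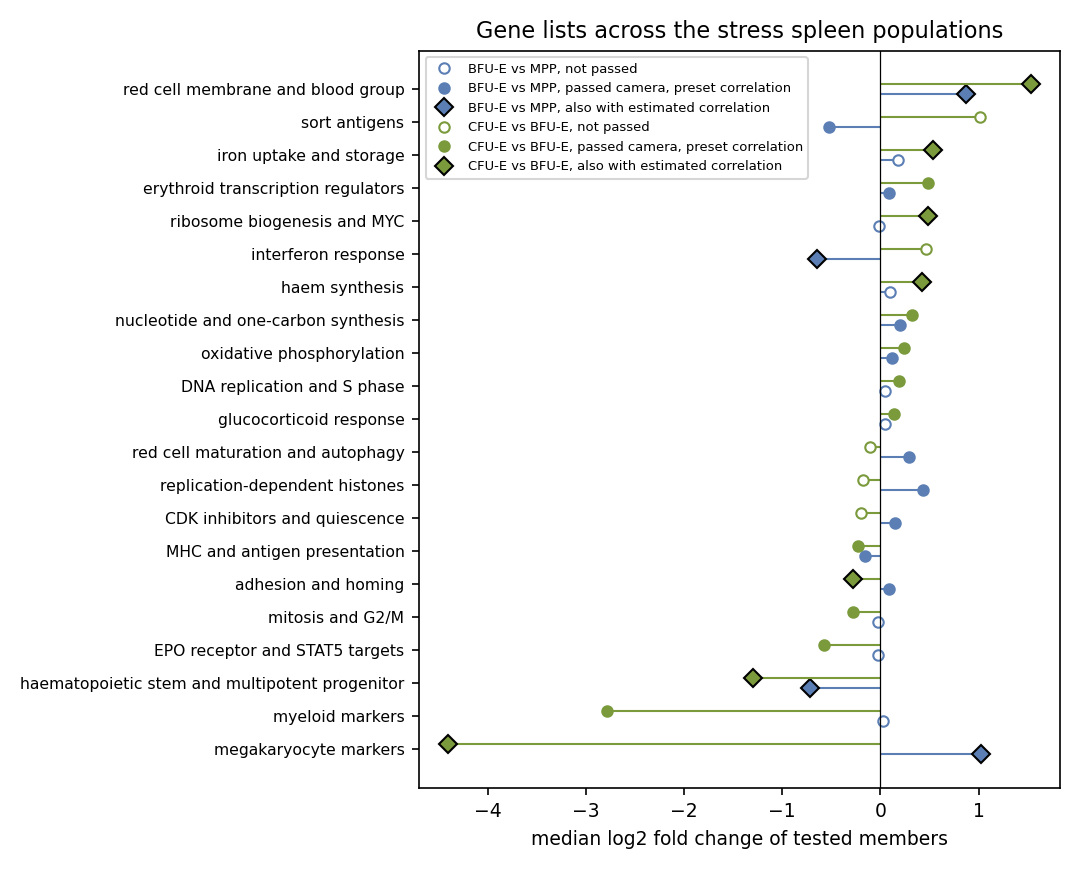
Median log2 fold change of the tested members of each list that passed camera in BFU-E against MPP or in CFU-E against BFU-E; filled circles passed at the preset correlation, diamonds also with an estimated one, open circles did not pass. The megakaryocyte markers had a median of 1.02 at the first step and of −4.40 at the second.

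CFU-E against MPP spans both steps, and 2924 genes differed, 1294 higher and 1630 lower in CFU-E (edgeR, BH). At an unadjusted p under 0.05 there were 3896, and in 4106 genes (40.4%) the groups did not overlap, where chance gives 10%. Car1 rose by 7.75 on the log2 scale (SE 0.34, edgeR adjusted p = 4.5e-13), Ermap by 8.60, Klf1 by 3.63 and Il1rl1 by 5.43. The iron exporter Slc40a1 rose by 4.45. Mecom changed by −4.99 (edgeR adjusted p = 4.2e-12) and Timp3 by −9.49. The chaperone gene Clu had a count of 0 in all CFU-E libraries against 49.5 ± 10.6 CPM in MPP, which makes it at least 570-fold lower against a floor of 3 counts over the group. The class II antigen presentation gene H2-Eb1, also at 0, was at least 525-fold lower (45.6 ± 27.3 CPM in MPP). Kit did not differ between the ends of the path (0.19, edgeR adjusted p = 0.21).

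BM BFU-E could be set against MPP and CFU-E only on RPKM, in log2(RPKM + 1) with limma. The BM columns of the table with all populations differ from the BM columns of the table with both BFU-E populations, while the spleen BFU-E columns match, so each comparison depends on the table. Against MPP, 7766 of 11628 genes differed (5849 higher and 1917 lower in BM) with the former columns. With the latter, 689 of 11300 did, 683 of them among the 11628, which the counts below use. With both, 293 genes changed in the same direction and 201 in opposite directions, where independent lists would give 190 and 266; the MPP libraries are the same in both, which by itself favours the same direction. Against CFU-E, 7773 genes differed (6035 higher and 1738 lower) with the former, and 2037 of 11300 with the latter, 2024 of them among the 11628. With both, 948 changed in the same direction and 562 in opposite ones (634 and 719 for independent lists, again with the same CFU-E libraries in both). The median over all genes was 0.81 and −0.19 against MPP in the former and the latter columns, and 0.87 and −0.12 against CFU-E. Only genes called with both sets of columns are named, with the former value first. Against MPP, BM BFU-E had higher Pf4 (4.36 and 2.39), Itga2b (2.64 and 1.15), Csf1r (4.16 and 3.33) and Irf8 (6.08 and 3.77), and lower Procr (−2.19 and −2.37), Fgd5 (−2.42 and −1.72) and Hlf (−1.09 and −1.49). For Hlf the limma adjusted p was 0.015 and 0.023. Against CFU-E, BM BFU-E had higher Pf4 (10.55 and 8.58), Vwf (2.88 and 4.07), Lyz2 (8.61 and 4.97) and Cd9 (5.74 and 2.98), and lower Ermap (−5.21 and −4.58), Ank1 (−4.08 and −4.03) and Tfrc (−1.96 and −2.64). For Tfrc the limma adjusted p was 8.2e-05 and 5.6e-05. Of the lists, 14 of 18 megakaryocyte markers, 13 of 19 myeloid markers and 11 of 28 stem and multipotent progenitor genes were higher in BM BFU-E than in CFU-E with both sets of columns, and 5 of 15 red cell membrane genes were lower. Of 6 globin genes, 2 were lower in BM BFU-E than in MPP with both sets of columns and 0 differed from CFU-E with both.

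Where the BFU-E of each tissue stand between MPP and CFU-E was measured over 584 genes that differ between those ends, with 0 for MPP and 1 for CFU-E. Stress spleen BFU-E lay at 0.290 ± 0.058 and BM BFU-E at 0.141 ± 0.077 (SD, n = 3 each), and the difference of 0.149 gave p = 0.2 in an exact two-sided permutation test, where 0.1 is the smallest possible; with another pseudocount, a 2-fold choice of genes or TMM-rescaled RPKM the exact permutation p was 0.1. In the 99 genes higher in CFU-E the places were 0.187 and 0.0188, and in the 485 genes higher in MPP 0.320 and 0.193. Without genes of the myeloid, macrophage and antigen presentation lists and without genes at a lower level in stress than in BM BFU-E, the difference was 0.00518 (exact permutation p = 0.9), with BM at 0.286; leaving out the latter genes narrows it by construction. Without the list genes alone it was 0.136 (exact permutation p = 0.2), with BM at 0.156. Of the 11 genes lower in stress than in BM BFU-E, 6 were among the genes higher in MPP than in CFU-E, where independence gives 0.51 (Fisher's exact test across genes, odds ratio 25.03, BH adjusted p = 1.4e-05 over 8 tests). Genes are not independent replicates, so this p does not measure the spread between libraries. The set of called genes was also unstable, with 0 called without stress spleen BFU-E 2 or without stress spleen BFU-E 3.

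Accessible chromatin marks promoters and enhancers that are open to regulators. The peak list of stress spleen BFU-E held 61661 peaks and that of BM BFU-E 35142. Of the stress peaks 33921 (55.0%, 95% Wilson interval 54.6 to 55.4) overlapped a BM peak, and of the BM peaks 33552 (95.5%, 95.3 to 95.7) overlapped a stress peak, which left 27740 and 1590 peaks in 1 list alone. With the stress list cut to its 35142 highest-scoring peaks, as many as the whole BM list, 6698 stress and 6699 BM peaks lacked a partner. Equal list lengths hold these numbers close together. Since 1590 BM peaks lacked a stress peak before the cut, most of those 6699 overlapped a stress peak that was cut. The covered length was 41765441 bp in stress and 29162657 bp in BM. Each list is 1 merged call without libraries to compare and with an unknown depth, so a difference in peaks could not be tested against the spread between replicates. Peaks within 1 kb of a TSS made up 22.9% of the stress list and 33.3% of the BM list, but 8.63% of the stress-only and 8.11% of the BM-only peaks. The stress list held 1.75 times the peaks of the BM list in all, which the numbers per gene are to be read against. Around Kit there were 6 peaks in BM and 12 in stress, around the GATA1 cofactor gene Zfpm1 10 and 20, around the globin switch regulator Bcl11a 13 and 21, and around Tal1 4 and 8. For the BMP target genes Id1 and Smad6 the numbers were 3 and 6, and 7 and 10. Klf1 (1 and 1), Epor (2 and 2), Tfrc (3 and 3) and the myeloid regulator Spi1 (2 and 2) had equal numbers. Among the stress-only peaks with the top score of 1000, shared by 4124 of them, was an intron of Etv6, a repressor needed in blood stem cells (chromosome 6, 134151850 to 134152540). A BM-only peak with that score, shared by 28, was annotated to Mia3 (chromosome 1, 183370042 to 183370262).

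**Figure D4:**
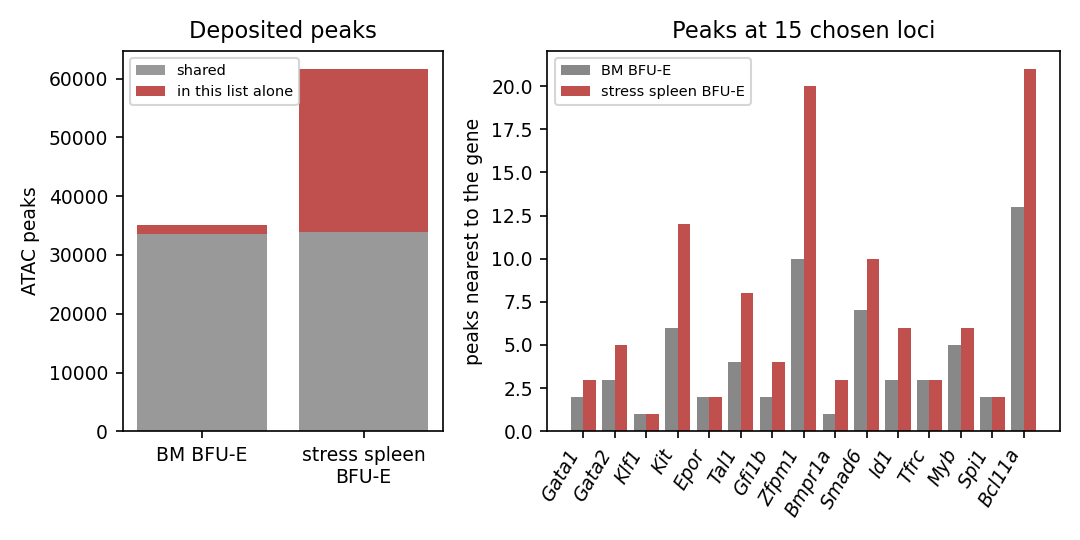
Number of deposited ATAC peaks of BM and stress spleen BFU-E, split into peaks shared with the other list and peaks in this list alone (left), and number of peaks nearest to each of 15 genes (right). The stress list, 1.75 times as long, held 27740 peaks of its own and the BM list 1590, and Kit had 12 peaks in stress against 6 in BM. With the stress list cut to its highest-scoring peaks, as many as the whole BM list, 6698 stress and 6699 BM peaks lacked a partner. Most of the latter overlapped a stress peak that was cut.

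The motifs of blood regulators were counted in distal peaks, 25347 stress-only and 1461 BM-only. Among equal numbers of peaks, the BM-only peaks include many that overlapped a stress peak left out by the cut. The GATA motif, bound by GATA1 and GATA2, was in 34.6% (95% Wilson interval 34.0 to 35.2) of stress-only and 27.4% (25.2 to 29.8) of BM-only peaks (log2 odds ratio 0.49, Fisher's exact test, BH adjusted p = 8.3e-08 over 72 tests). In promoter peaks it was in 16.3% of 2393 stress-only and 23.3% of 129 BM-only peaks (log2 odds ratio −0.64, BH adjusted p = 0.148), and among equal numbers of the highest-scoring peaks in 17.6% and 12.6% (0.58, BH adjusted p = 0.024). The motif of CTCF, which bounds chromatin loops, was in 6.98% against 3.15% (1.21, BH adjusted p = 5.2e-09), and among equal numbers of the highest-scoring peaks in 7.22% against 5.11% (0.53, BH adjusted p = 1.9e-05). KLF motifs were in 10.5% against 7.94% (0.44, 0.0071), but their log2 odds ratio was 0.03 (adjusted p = 0.946) in peaks of equal GC content. E-box motifs were in 45.7% against 41.9% (0.22, 0.015), but at 0.07 (adjusted p = 0.401) among equal numbers of the highest-scoring peaks. ETS or PU.1 motifs, bound by regulators of myeloid cells, were in 5.69% and 5.68% (adjusted p = 1). RUNX, AP-1, NFE2, STAT, IRF, NFY and glucocorticoid receptor motifs did not pass. Promoter and distal peaks together, BM-only peaks had a median score of 523 and stress-only peaks of 736. No motif test matched peaks on score, so these shares may also follow the strength of the peaks. The genes nearest to stress-only peaks had a median RNA log2 fold change of −0.0047 (5266 genes, stress against BM) and those nearest to BM-only peaks −0.077 (145 genes). The difference of 0.0719 gave p = 0.289 in a permutation test across genes, which are not independent replicates.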

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

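No sample or result met the criteria for an extreme sample, for effects that differ between groups or for signal in unused data; 3 patterns in the BM data were weighed, and the tests of a rescaled table, of RNA capture, of noise, of myeloid cells, of single BM libraries as the source of the spread and of other splits were chosen only after the results were seen. For the swap of columns and for 1 BM library behind the myeloid genes, the value that decides was also chosen after, in place of the planned one.

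The BM columns of the RPKM table of all populations differ from those of the table of both BFU-E populations, while the spleen BFU-E columns match. A rescaling by a factor per library is argued against by the smallest SD over genes of the log2 ratio, 1.15786 in BM against at most 0.0247 in spleen. A swap of BM and spleen columns is argued against, since each spleen column matched itself across tables at r of at least 0.999782; the planned swap test gave 0.0848, the way a swap would, but it looked at BM columns alone. Shares of RNA were taken from RPKM multiplied by gene length. Replication-dependent histones, whose messages carry no poly(A) tail, took at least 22.531 times the share in the BM columns of the smaller table. The lowest share there was 0.715%, against at most 0.0317% in the larger table, with 0.883% to 1.05% in spleen BFU-E. A different capture of RNA would give such a gap. The BM columns of the larger table may therefore come from other libraries made on poly(A) RNA. Whether the cells also differed in their biology was not tested.

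The myeloid markers were higher in BM than in stress spleen BFU-E, with a median log2 fold change of −1.51 in stress. A source in 1 BM library is argued against, since BM 2 and BM 3 had medians of 2.19 and 1.94101 above spleen; the planned value, the lowest library median (−0.055, BM 1), would have been met by any library without the change. Capture of RNA could not be decided. In the BM columns of the larger table, 17 of 17 members were higher and the list lay 2.36447 above the median of all genes. There, however, BM and spleen BFU-E columns seem to differ in capture themselves. Their ribosomal RNA shares, also from RPKM multiplied by gene length, were 0.12% to 0.21% and 10.7% to 11.5%. Noise that moves these genes together stays open: 0% of 10000 random lists of like genes had so low a median, but such lists lack the correlation within the myeloid list, and with that correlation estimated camera gave p = 0.0838483 (adjusted p = 0.33). Myeloid cells in the BM gate may also contribute. Of 8 members picked as abundant in such cells, 8 were higher in BM, by unequal amounts (Ly6c2 −3.38, Csf1r −3.31, Irf8 −2.84, Lyz2 −2.40, Elane −0.61, Prtn3 −0.50, Mpo −0.45 and Ctsg −0.40 in stress, with Csf1r alone past the edgeR threshold). Outside those 8, Ltf alone of the list went the other way (0.78), and Ngp (−0.04) and S100a9 (−0.29) changed least. With nearly the whole list higher in BM, 8 of 8 was likely for any pick, so this count cannot decide. Near list genes, 20 peaks were shared between the lists, 14 were in stress alone and 0 in BM alone. These peaks do not bear on the question, since 95.5% of all BM peaks were shared. Depletion of Gr-1 would remove granulocytes, and a myeloid program within the BM BFU-E was not tested.

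The BM libraries spread far more widely than the spleen BFU-E libraries, with a common dispersion of 1.03 against 0.0608. Spleen libraries thinned to the BM totals had a dispersion of 0.0539367. Random thinning leaves this measure nearly unchanged by construction, so that value cannot decide on depth. The share of genes with a count of 0 was 0.420% to 0.822% after thinning, against 1.53% to 15.3% in BM. This argues against smaller depth as the source of the zeros in BM. A single BM library is argued against, since the dispersion stayed at 0.585676 without BM 3, at 1.29 without BM 1 and at 1.43 without BM 2. Few starting molecules could leave such a spread: in BM the dispersion of the genes with the lowest counts was 42.2157 times that of the genes with the highest, which met the bound written before, but in spleen it was 25.7 times, so this stays open. Variation between animals or sorts of the BM samples was not tested.

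For each comparison of 3 against 3 libraries, 10 splits are too few for a share under 0.05, and 1 of them, the real split, gave as many genes as the real one. The real value and the highest of the other splits were 12 and 0 genes for stress spleen against BM BFU-E, 470 and 5 for BFU-E against MPP, 2410 and 0 for CFU-E against BFU-E and 2555 and 0 for CFU-E against MPP, each fitted in edgeR on 6 libraries alone. On RPKM in limma they were 6709 and 0 for BM BFU-E against MPP and 6841 and 0 against CFU-E. The genes of stress spleen against BM BFU-E appear to have been kept on the means of the real groups, which can favour the real split there.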

How the results depend on the processing

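The alternatives chosen only after the data were seen were voom with quality weights, DESeq2 with a mean dispersion trend, limma on the RPKM of both BFU-E populations, fits without non-coding RNA, the BM columns of that table, the place without myeloid, macrophage and antigen presentation genes, alone or with stress-lowered genes, and peaks of equal GC content. Besides the fits without 1 library, 233 alternative values were made for 46 values, namely the numbers of called genes and lists, the places, the shares of peaks, the motif odds ratios and the RNA difference by accessibility. Of these 165 kept their direction, side of the threshold or size, 64 moved, 2 motifs lost and 1 gained a call, and 1 motif reversed; single genes, and the lists one by one, are not in these numbers. Where a value changed below, the cause was not tested unless a cause is given.

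For stress spleen against BM BFU-E (12 genes, 1 higher and 11 lower in edgeR), DESeq2 called 685 (264 and 421), with a mean trend 579 (243 and 336), both holding all 12. Voom called 181 (26 and 155), and limma on the RPKM of all populations 7339 (1804 and 5535), where the BM columns are other values. limma on the RPKM of both BFU-E populations called 14 genes, 2 of them higher, and held 8 of the 12. With the replicate number as a block, 3 were called (0 and 3). Without 1 library the count ran from 0 (without stress spleen BFU-E 2; 481 at an unadjusted p under 0.05) to 27 (without BM 3), higher 0 to 5 and lower 0 to 22. Of the 9 named genes 0 kept their call without every library in turn and 1 kept it under every other alternative. On the RPKM of all populations, Itsn1 was reversed at 0.75 (limma adjusted p = 0.17), as were Ldha (−2.27) and Atp5b (−2.07), which had not passed in edgeR. Against 12 lists (4 higher and 8 lower), 0 were called with an estimated correlation (0 and 0), and fry called 3 (2 and 1), 2 of them among the 12; without 1 library 5 (without BM 2) to 12, higher 2 to 5 and lower 3 to 8.

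For BFU-E against MPP (420 genes), a minimum of 2-fold called 194 (67 and 127), no filter on low counts 668 (311 and 357) and RPKM in limma 56 (27 and 29). DESeq2 called 619, 327 of them lower. Without 1 library the count ran from 225 (without BFU-E 1) to 458, higher 109 to 213 and lower 116 to 245. With an estimated correlation 4 lists were called (2 higher and 2 lower), and fry called 5 higher; without 1 library 10 to 14, higher 6 to 9 and lower 4 to 5. For CFU-E against BFU-E (2145), a minimum of 2-fold called 965 (257 and 708) and RPKM 686 (252 and 434); without 1 library 1649 to 2340, higher 671 to 1061 and lower 978 to 1279. An estimated correlation called 7 lists (4 and 3), and fry 12 lower; without 1 library 15 to 17, higher 8 to 10 and lower 5 to 8. For CFU-E against MPP (2924), a minimum of 2-fold called 1376 (353 and 1023) and RPKM 1120 (391 and 729); without 1 library 2321 to 2785, higher 964 to 1230 and lower 1357 to 1555. A minimum of 2-fold lowers a count by construction. Of 42, 56 and 14 named genes of these comparisons, 31, 54 and 14 kept their call without every library in turn, and 15, 37 and 13 under every other alternative.

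BM BFU-E against MPP gave 689 (235 and 454) with the BM columns of the other RPKM table, and against CFU-E 2037 (911 and 1126). Without 1 library these ran from 7217 to 8135 (higher 5446 to 6185, lower 1677 to 2196) and from 7043 to 8107 (higher 5471 to 6344, lower 1489 to 1937). The place of BM BFU-E moved to 0.286 without genes of the myeloid, macrophage and antigen presentation lists and without stress-lowered genes; leaving out the latter narrows the difference by construction. Without the list genes alone it was 0.156 (difference 0.136, exact permutation p = 0.2). It was 0.0820 with the BM columns of the table of all populations (difference 0.208, exact permutation p = 0.2) and 0.110 on TMM-rescaled RPKM (difference 0.201, exact permutation p = 0.1); with another pseudocount or a 2-fold choice of genes the exact permutation p was 0.1. Without 1 library the difference ran from 0.119 to 0.192, BM from 0.0976 to 0.171 and stress from 0.265 to 0.322. The share of BM peaks found in stress was 90.4% with a reciprocal overlap of 0.5 and 96.4% in the highest-scoring part of each list. It was 80.9% with the stress list cut to the length of the BM list, where BM peaks could lose their partner by the cut. For stress peaks the share was 51.5% with the reciprocal overlap and 80.9% with the cut. With equal numbers of peaks E-box lost its call (log2 odds ratio 0.066) and NFY gained one (0.289), and at equal GC content KLF lost its call (0.027). GATA in promoter peaks, at −0.64 and not called, was reversed at 0.577 and called with equal numbers of peaks.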

Other observations

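The simulation of shared libraries was planned; the test of separate against shared BFU-E libraries was chosen only after the result was seen, and the genes named here were picked after their values were seen. Some genes peak in stress spleen BFU-E and lie lower on either side of the path. Among 10166 genes, 79 rose from MPP to BFU-E and fell from BFU-E to CFU-E in edgeR. Some of them serve platelets and megakaryocytes. Plek, which acts in platelet activation, was at 192 ± 46.0, 505 ± 21.5 and 13.5 ± 2.23 CPM in MPP, BFU-E and CFU-E, and Pf4 was at 97.6 ± 6.62, 272 ± 39.4 and 0.359 ± 0.482. The urea transporter gene of the Kidd blood group, Slc14a1, was at 187 ± 20.04, 467 ± 30.7 and 131 ± 24.98 CPM, and the spectrin gene Sptb at 21.7 ± 11.9, 80.0 ± 10.7 and 21.5 ± 4.303. In the other direction, 39 genes fell to BFU-E and rose again. Cd24a was at 111 ± 14.3, 35.7 ± 6.51 and 175 ± 30.6 CPM, and the growth factor receptor adaptor Grb10 and the regulator Mllt3 had the same shape. A further 45 genes rose and 65 fell at each step.

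A shape with BFU-E at the top could come from the BFU-E libraries being used in both comparisons, since noise that raises a gene in BFU-E raises it against both neighbours. Independent calls would give 24.6 genes of this shape, against 79 observed, but the other shapes lie above independence too (45 against 18.9 for a rise at each step, 65 against 25.5 for a fall at each step, 39 against 19.6 for the opposite shape), so an excess alone does not point to BFU-E. In 20 simulations of unchanged groups with shared BFU-E libraries the mean was 0, below the bound written before, but that test was void: edgeR called a mean of 0 genes in each comparison, so none could be called in both, whether or not libraries were shared. The calls were therefore repeated with 1 BFU-E library in a comparison and 2 in the other, where a lone library is assumed to vary like the other groups. With no library in both comparisons 23 to 48 genes had the shape over 6 ways, and with 1 library in both 23 to 49 over 12 ways, with the same numbers of libraries; the lowest ratio of the former to the mean of the latter was 0.909091. For the genes that these smaller fits called, this argues against shared libraries as the whole source of the shape; for the rest of the 79 genes it stays open. Cd24a and Cd9, which is among the 79 genes, were also antigens of the sort, so their shapes, and those of genes that vary with them, may follow the gates.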
